A study of Danio rerio with 2 samples.

How the data were processed

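The series holds 2 single-cell RNA-seq libraries of zebrafish (Danio rerio), 1 from embryos at 28 hours post fertilization (hpf) and 1 from embryos at 52 hpf. Per the labels' protocols, mothers carrying a prop1:GAL4 driver and a UAS reporter for membrane-bound red fluorescent mScarlet were mated to wild-type AB males, and the offspring were chilled, anaesthetised and dissected by hand. The torso was largely taken off the younger embryos, and the heads of the older embryos were separated from the body. DAPI was added, the cells were sorted by flow cytometry, and dissected siblings without fluorescence set the negative control of the sort. Each library was made on its own lane of a Chromium controller with the 10x Genomics 3′ kit v3.1 and sequenced on a NextSeq 2000, per the labels' protocols. The labels give both libraries the tissue pituitary and the genotype wt.

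The deposited matrices hold counts: whole numbers of unique molecular identifiers (UMIs) per gene and cell barcode, with no normalization. Per the labels' protocols, the authors aligned the reads with Cell Ranger 9.0.1 to zebrafish assembly GRCz11, to which they added sequence of the transgenic lines. The submitters' processing notes also name Scanpy 1.11.0, with no step given. The rule by which barcodes were called cells is not given in the sources used here. The gene tables hold 32057 gene identifiers. The 734 entries that repeated a symbol were summed by symbol, which left 31323 symbols, and lhx3 appears as LHX3. The symbols mScarlet, Gal4, GAL4 and UAS were searched for and matched no entry, so transgene transcripts were not analysed here. No coordinates are given, since no genome of this assembly was used.

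Grouping was by age. With 1 library per group there was no replicate, so no test was run and no p-value or standard error is given. Values are set side by side with 95% intervals: exact Poisson limits for summed UMIs, exact Clopper-Pearson limits for shares of cells, and exact conditional binomial limits for ratios of summed UMIs. These intervals and the detection limits, set at 3 counts where a count was 0, cover counting error only. They take no account of embryos, dissection, sorting or library preparation, and cells are not replicates.

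Cells were kept with at least 500 genes and at most 10% of UMIs from the 13 mitochondrial genes, after which doublets predicted by Scrublet (as in Scanpy, expected rate 0.06, run per library) were removed. Scrublet predicted 7 doublets among 1553 barcodes at 28 hpf (0.451%) and 3 among 2976 at 52 hpf (0.101%), far below the expected rate, so few doublets were removed. An alternative chosen after seeing the data took out the 6% of cells with the highest doublet scores as well. Counts per 10⁶ UMIs (CPM) were computed over all genes except the mitochondrial ones. Kept cells held 28443560 such UMIs at 28 hpf and 40444956 at 52 hpf.

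Both libraries were clustered together without batch correction: 10000 counts per cell, log transform, 2000 variable genes chosen within each library, 30 principal components, 15 neighbours and Leiden clustering at resolution 1.0, which gave 31 clusters. Clusters were named from 28 sets of marker genes fixed before the data were examined. A name needed at least 3 of its markers detected in 25% of the cluster's cells with a log2 ratio of at least 1 to the other cells. A class was compared between libraries only where no cluster of it had more markers of another class than of its own among its 10 leading genes. The epidermis-like, neural progenitor-like and retina-like classes failed that check and were not compared. Hormone-rich cells were defined separately, as cells in which 1 hormone gene held at least 1% of UMIs.

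Levels were compared as log2 ratios of CPM with a pseudocount of 5 CPM, which understates the ratio of genes with few UMIs. A gene was called higher or lower at a 2-fold difference (log2 ratio of 1 or more in size) whose counting interval excluded no difference, a rule of size and not a test. Of 21 gene lists fixed before the data were examined, 13 of the 717 list and marker entries matched no symbol. A list was summarised over its members at 20 CPM or more in either group where at least 5 were measured, by its median and by the percentile of that median among 10000 random lists of equal size drawn from 20 expression bins, as a description of these libraries. Genes were named by a rule fixed before the data were examined: the 15 highest and the 15 lowest log2 ratios among genes with at least 50 CPM in either group and 30 UMIs in all, without ribosomal protein, mitochondrial and globin genes, and the 10 highest for each hormone. Also named were prop1, the pituitary hormones, the pituitary transcription factors and the most different members of the other lists. Hormone-rich cells were compared with progenitor-like cells rich in no hormone where at least 20 cells were rich in that hormone alone.

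Shares of cells with a UMI were also computed after thinning each cell to 6000 UMIs, the lower of the libraries' 10th percentiles rounded down to a multiple of 100, and shallower cells were left out. Alternatives were fixed before the data were examined: no cell filter, a stricter filter (1000 genes, 5% mitochondrial UMIs), doublets kept, median-of-ratios scaling over genes with at least 50 UMIs in each group, a total without hormone, globin and ribosomal protein genes, pseudocounts of 1 and 20 CPM, no gene filter, thinned cells, hormone thresholds of 0.5% and 2%, Leiden resolutions of 0.5 and 2.0, and clustering without hormone and cell cycle genes. The shift of all genes between scalings was largest in pituitary-like cells. There the median log2 ratio over 5968 genes was 0.201 with totals, −0.070 with median-of-ratios scaling and 0.052 without hormone, globin and ribosomal protein genes.

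The comparison step was tested on simulated Poisson counts, drawn around the pooled mean of each gene, in which 200 genes had been changed. Those counts hold no variation between cells, embryos or libraries, so they check the computation and give no error rate for these data. For the whole library 0 of 4751 unchanged genes were called and the intervals covered the true ratio in 95.4% of genes. For pituitary-like cells the values were 0 of 4768 and 95.2%. In the comparison of prl-rich with progenitor-like cells at 52 hpf, 36 of 5380 unchanged genes were called and coverage was 94.6%. In each of these simulations 100% of the 80 genes changed 3-fold and of the 80 changed 6-fold were called, and 0% of the 40 changed 1.5-fold. Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, Scanpy 1.11.5, anndata 0.12.19, scikit-learn 1.9.0, leidenalg 0.10.2, python-igraph 0.11.9 and matplotlib 3.10.9 were used, with random seed 1.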

Results

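Reporter-positive cells were sorted from prop1:GAL4;UAS:mScarlet-CAAX zebrafish embryos at 28 and 52 hpf, in order to follow early pituitary development by single-cell RNA-seq. prop1 encodes a homeodomain transcription factor of the developing anterior pituitary. There was 1 library per age, so every comparison describes 2 libraries and has no replicate check. The 28 hpf library held 28735665 UMIs in 1553 barcodes, of which 1546 cells were kept, with medians of 16080 UMIs and 3195 genes per cell and 0.364% mitochondrial UMIs. The 52 hpf library held 40818799 UMIs in 2976 barcodes, of which 2972 cells were kept, with medians of 10503.5 UMIs, 2582.5 genes and 0.706% mitochondrial UMIs. The shallowest barcodes had 4625 and 4743 UMIs.

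prop1 (ENSDARG00000039756), the locus of the driver, was read first in both libraries. It stood at 172 CPM (95% counting interval 167–177) at 28 hpf and 27.1 CPM (25.5–28.7) at 52 hpf, 6.34-fold higher in the 28 hpf library. A prop1 UMI was found in 594 of 1546 cells at 28 hpf (38.4%, 36.0–40.9) and in 161 of 2972 at 52 hpf (5.42%, 4.63–6.29). Thinned to 6000 UMIs per cell, with 40 and 295 shallower cells left out, the shares were 28.2% and 4.48%. Pituitary progenitor-like clusters were named partly by prop1, so its level there is conditioned on the gene itself: 388 CPM at 28 hpf and 543 CPM at 52 hpf, with UMIs in 74.0% and 75% of cells (57.5% and 64.3% thinned). In pituitary hormone-cell-like cells it stood at 86.5 CPM at 28 hpf and 11.1 CPM at 52 hpf, with UMIs in 23.9% and 7.39% of cells (13.1% and 5.61% thinned). Of those 538 UMIs at 28 hpf, 469 came from cluster 27 (54 cells, 270 CPM), whose cells may be attached pairs, and without it (chosen after seeing the data) prop1 stood at 15.4 and 10.3 CPM and passed no 2-fold limit. Outside pituitary-like clusters, where UMIs may be free RNA, a prop1 UMI was present in 8.90% of cells at 28 hpf and 1.09% at 52 hpf (4.28% and 0.755% thinned). The shares were 2.2% and 0.538% in neural crest- or mesenchyme-like cells (1.12% and 0.279% thinned), but 17.5% in epidermis-like cells at 28 hpf (6.64% thinned), a class whose name was less certain. Median depths of the neural crest- or mesenchyme-like cells were 16963 and 10308 UMIs, against 15037 and 10290.5 for progenitor-like cells.

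The cell classes asked what the sort had collected at each age. Pituitary-like cells, progenitor-like and hormone-cell-like together, were 962 of 1546 cells at 28 hpf (62.2%, 59.8–64.6) and 496 of 2972 at 52 hpf (16.7%, 15.4–18.1). Progenitor-like cells, named from markers such as prop1, LHX3, pitx3, six1b and hesx1, were 40.3% (37.8–42.8) of the 28 hpf library and 4.85% (4.1–5.68) of the 52 hpf library. Hormone-cell-like cells were 21.9% (19.9–24.1) and 11.8% (10.7–13.1). Neuron-like cells, with elavl3 and elavl4, were 1.23% (0.742–1.91) at 28 hpf and 18.1% (16.8–19.6) at 52 hpf. Neural crest- or mesenchyme-like cells were 11.8% and 12.5%. Cartilage-like cells were 0 of 1546 at 28 hpf (detection limit 0.194%, exact upper limit 0.238%) and 4.41% at 52 hpf, and myeloid-like cells were 0.194% and 2.66%. Clusters were mostly of 1 library each, so a cluster may be that library and not a type: progenitor-like cells were clusters 0 and 10 at 28 hpf and cluster 9 at 52 hpf, hormone-cell-like cells clusters 7, 15 and 27 at 28 hpf and clusters 14, 17, 24 and 25 at 52 hpf. Clustering without hormone and cell cycle genes gave pituitary-like shares of 61.8% and 16.7%. The shares also carry the sort gate and the dissections, which differed between the ages, and 1 cluster that could not be named held 3.49% and 2.69% of cells.

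**Figure D1:**
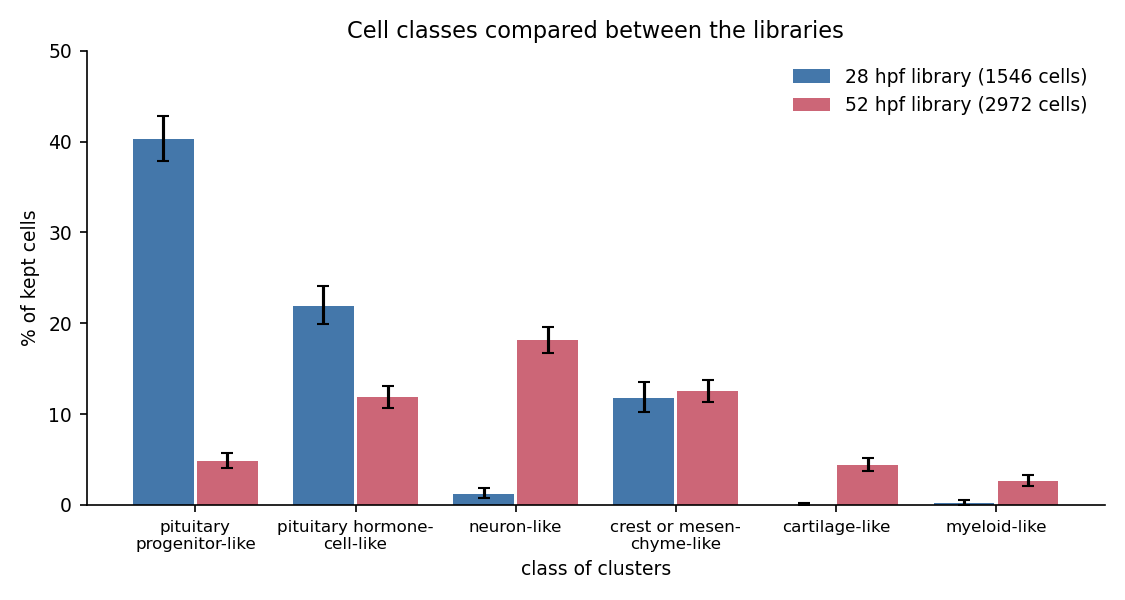
Share of kept cells (%, y axis) in each compared class of clusters (x axis) in the 28 hpf library (blue, 1546 cells) and the 52 hpf library (red, 2972 cells), with exact 95% binomial intervals for counting error only as error bars. Progenitor-like cells took 40.3% and 4.85% of the libraries and neuron-like cells 1.23% and 18.1%.

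Hormone transcripts were then compared over all kept cells, which needs no clustering. Prolactin (prl, ENSDARG00000037946) stood at 2589 CPM (2570–2608) at 28 hpf and 686 CPM (678–694) at 52 hpf, 3.78-fold higher in the 28 hpf library (3.72–3.83). The transcripts of 4 other hormone genes were higher in the 52 hpf library. The thyrotropin beta subunit tshba (ENSDARG00000033726) had 595 CPM against 152 at 28 hpf, 3.91-fold higher (3.78–4.04). The proopiomelanocortin gene pomca (ENSDARG00000043135) had 458 against 59.4 CPM, 7.70-fold higher (7.33–8.10), and the shared glycoprotein hormone alpha subunit cga (ENSDARG00000040479) 168 against 14.4 CPM, 11.6-fold higher (10.5–12.9). Growth hormone (gh1, ENSDARG00000038185) had 193 CPM at 52 hpf and 0 UMIs at 28 hpf, 1827-fold above a detection limit of 0.105 CPM (exact lower limit of the ratio 1485-fold). Of its UMIs at 52 hpf, 25.9% came from 1 cell. Both somatolactin genes, pituitary hormones of fish, were lower in the 52 hpf library: smtla (ENSDARG00000038191) stood at 153 CPM at 28 hpf and 1.58 CPM at 52 hpf, 96.6-fold (75.5–126), and smtlb (ENSDARG00000017251) at 124 and 12.4 CPM, 9.98-fold (9.09–11). The gonadotropin beta subunits had 4 UMIs (lhb, 52 hpf alone) or none (fshb), prl2 had 2 UMIs in each library, and pomcb had none.

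Because the pituitary-like share differed between the libraries, the same genes were also read over UMIs of pituitary-like cells alone, a choice made after seeing the data. There prl passed no 2-fold difference, with 4763 CPM at 52 hpf and 4313 CPM at 28 hpf. tshba was 17.0-fold (16.4–17.6), pomca 34.1-fold (32.4–35.8) and cga 50.7-fold (45.9–56.2) higher at 52 hpf, and gh1 stood 7291-fold above the level of 3 UMIs (exact lower limit of the ratio 5928-fold). smtla was 33.9-fold (24.8–47.8) and smtlb 2.24-fold (2.04–2.47) higher at 28 hpf. A few cells carry the smtlb level at 52 hpf: of 478 UMIs, 249 came from 3 smtlb-rich cells and 105 from 1 other, progenitor-like cell. Pituitary-like cells also differed in make-up: 339 of 962 were hormone-cell-like at 28 hpf and 352 of 496 at 52 hpf. Over hormone-cell-like cells alone, prl stood at 11785 CPM at 28 hpf and 6741 CPM at 52 hpf, the reverse order. There tshba stood at 694 and 6330 CPM and pomca at 257 and 4768 CPM. In those cells cga was 27.4-fold higher at 52 hpf and smtlb 5.29-fold higher at 28 hpf. Hormone RNA, part of which may be free, was also found outside pituitary-like clusters. A prl UMI was present in 17.6% and 11.8% of cells at 28 and 52 hpf (6.06% and 5.55% thinned). A tshba UMI was present in 1.2% and 10.9% (0.357% and 5.33% thinned) and a pomca UMI in 0.171% and 8.16% (0.178% and 3.69% thinned).

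**Figure D2:**
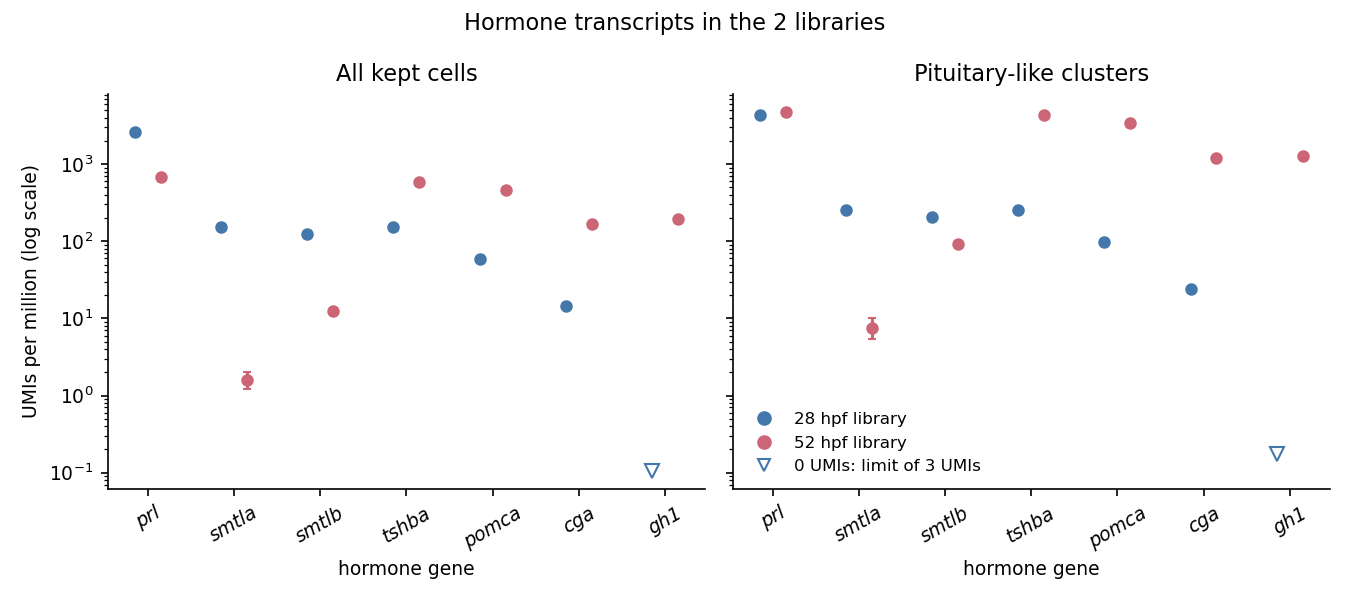
Level in CPM (log y axis) of 7 hormone genes (x axis) in the 28 hpf library (blue) and the 52 hpf library (red), over all kept cells (left) and over pituitary-like clusters (right), with exact Poisson 95% intervals and an open triangle at the level of 3 UMIs where 0 UMIs were seen. prl was 2589 and 686 CPM over all cells but 4313 and 4763 CPM over pituitary-like clusters.

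The cells that carried these transcripts were counted as hormone-rich cells. At 28 hpf they were nearly all rich in prl: 122 cells (7.89% of 1546, 6.60–9.35) against 6 rich in tshba (0.388%), 1 in pomca, 1 in smtlb and 0 in gh1 or cga (detection limit 0.194%, exact upper limit 0.238%). At 52 hpf pomca-rich cells numbered 66 (2.22% of 2972, 1.72–2.82), tshba-rich cells 59 (1.99%, 1.51–2.55), prl-rich cells 49 (1.65%, 1.22–2.17), cga-rich cells 11 (0.370%), gh1-rich cells 9 (0.303%) and smtlb-rich cells 3. As shares of pituitary-like cells, prl-rich cells were 12.7% at 28 hpf and 8.47% at 52 hpf, tshba-rich cells 0.624% and 11.5%, and pomca-rich cells 0.104% and 13.3%. No cell was rich in lhb, fshb or smtla. Cells rich in more than 1 hormone were 2 of 128 at 28 hpf and 13 of 184 at 52 hpf, of which 7 were rich in tshba and cga, 4 in prl and tshba and 2 in tshba and pomca. Being rich is a range and not a type, and between 0.5% and 2% of UMIs lay 36 cells for prl at 28 hpf and 19 for prl, 18 for tshba, 27 for pomca and 48 for cga at 52 hpf. Removing the 6% of cells with the highest doublet scores, chosen after seeing the data, left the gh1-rich share at 0.143%, and 10 of the 184 rich cells at 52 hpf lay outside pituitary-like clusters, with a median of 19995.5 UMIs against 8029 for the 174 inside.

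Over all sorted cells, the genes lowest at 52 hpf relative to 28 hpf included pituitary hormone and transcription factor genes, and those highest included genes of retina, cartilage, nervous tissue and epidermis and heat shock genes, beside pituitary-like shares of 62.2% at 28 hpf and 16.7% at 52 hpf. The 15 lowest log2 ratios (52 over 28 hpf) were those of smtla (−4.58), the parvalbumin pvalb2 (−4.18), the elastase-like gene cela1.6 (−4.07), si:ch73-380l10.2, defbl1, the troponin tnnc1b (−3.55), actc1c, the chemokine cxcl12b (−3.23), the RNA-binding let-7 inhibitor lin28a (−3.19), smtlb (−2.89), the basement membrane gene nid2a, the carboxypeptidase gene cpm, prop1 (−2.46), the Wnt receptor fzd8a (−2.42) and pvalb8 (−2.33). The 15 highest were those of gh1, the heat shock genes hsp70l (5.26), hsp70.2 (4.59) and hsp70.1 (4.47), the retinal transcription factors vsx1 (4.95) and crx (4.29), the chemokine ccl34b.1 (4.90), the cartilage collagen col2a1a (4.85), the radial glial gene fabp7a (4.81), the neuronal membrane gene gpm6ab (4.74), zgc:136930, pvalb5, the epidermal genes icn2 (4.29) and krtt1c19e (4.27), and s100t.

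Among the fixed lists over all sorted cells, anterior pituitary transcription factors stood out for members lower at 52 hpf: of 31 measured, 12 were lower and 5 higher (median −0.49, below all 10000 random lists, percentile 0). The lower ones were prop1, pitx3 (−2.11), six3b (−2.08), the lineage factor pou1f1 (25.1 CPM at 52 hpf against 121, −2.07), nkx2.2a, ascl1a, six1b, lhx4, eya1, LHX3, insm1b and six4b. neurod4 (2.65), gata3, neurod1 (1.42), isl1 and sox9b were higher. Pan-neuronal genes were higher in 16 of 20 (median 1.53, percentile 100), led by elavl4 (383 against 24.1 CPM), and secretory granule genes in 7 of 14 with scg3 lower (median 1.08). Notch (5 of 26 lower, 3 higher, median −0.51), FGF (4 of 15 lower, median −0.59) and epithelial junction genes (5 of 20 lower, 1 higher, median −0.44) had medians below the central 95% of random lists. Wnt genes (3 of 9 higher, median 0.66) and the dissociation stress and immediate early list (10 of 31 higher, median 0.55) had medians above it. No DNA replication (23 measured, median −0.35, percentile 0.03) or mitosis gene (25, median 0.19) passed the 2-fold rule. Medians of Hedgehog (−0.03, with shha and shhb higher and nkx2.2a lower), BMP (0.25, 1 of 12 higher and 1 lower), oxidative phosphorylation (0.03), glycolysis (0.16), p53 (0.19) and globin genes (0.01, hbbe3 lower and hbbe1.1 higher) lay within the random range, and those of oxidative phosphorylation, p53 and globin genes turned negative under both other scalings, the p53 median with 8 measured genes in place of 9, since bcl2a fell below 20 CPM. Endoplasmic reticulum genes (median 0.20, 2 of 24 higher) lay at percentile 98.2. Fewer than 5 members were measured of the hormone-regulating receptors (thrb 1.23, higher, and nr3c1 0.53), the yolk and maternal-stage transcripts (apoc1 2.60, apoeb 2.47 and h1m 1.31 higher, ctsla 0.04) and the transgene list (prop1 alone).

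Within pituitary-like cells, most secretory granule genes measured were higher at 52 hpf and most cell cycle genes lower. Secretory granule and exocytosis genes were higher in 16 of 19 and lower in none (median log2 ratio 1.77, against −0.18 to 0.53 for 95% of random lists), led by chromogranin A (chga, 291 CPM at 52 hpf against 15.8, 3.83), syt1a (2.95), scg5 (2.74) and scg2b (2.72). DNA replication genes were lower in 16 of 20 (median −1.25, random range −0.13 to 0.58), among them pcna (143 against 345 CPM), fen1 (−1.77) and dut (−1.69). Mitosis genes were lower in 16 of 23 (median −1.08), among them mki67 (86.7 against 198 CPM) and cenpf (−1.52). Pan-neuronal genes, several of which serve exocytosis and are in both lists, were higher in 15 of 20 (median 1.83), led by rtn1b (4.04) and elavl4 (3.74), and glycolysis genes in 9 of 16 (median 1.29), led by gapdhs (884 against 255 CPM) and pgk1. These medians lay beyond all 10000 random lists. Hormone-cell-like cells were 339 of the 962 pituitary-like cells at 28 hpf and 352 of 496 at 52 hpf. Read within each class alone, chosen after seeing the data, the secretory median was 2.37 in progenitor-like and 1.29 in hormone-cell-like cells, and the DNA replication median −0.63 and −0.95. Fewer cell cycle genes passed the 2-fold rule there. DNA replication genes were lower in 6 of 22 in progenitor-like and 4 of 9 in hormone-cell-like cells, and mitosis genes in 3 of 25 in progenitor-like cells (median −0.60). Glycolysis genes were higher in 7 of 13 in progenitor-like cells (median 1.12) and in only 2 of 16 in hormone-cell-like cells (median 0.66). Hormone transcripts were higher in the progenitor-like cells at 52 hpf as well (prl 959 against 22.6 CPM, pomca 695 against 8.22 CPM), largely through a few cells: without hormone-rich cells the 52 hpf levels were 170 and 191 CPM, and in cluster 0 at 28 hpf 94.3% of the 87 pomca UMIs came from 1 cell. Hormone cells or their free RNA may therefore add to that secretory median. It was 2.15 over the 135 progenitor-like cells at 52 hpf that were rich in no hormone, which leaves free RNA open.

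Of 29 anterior pituitary transcription factors measured in pituitary-like cells, 7 were higher at 52 hpf, 3 lower and 19 passed neither limit (median 0.13, percentile 78.1, negative under both other scalings). The higher ones were isl1 (256 against 48.2 CPM, 2.29), gata2a (214 against 49.0, 2.02), neurod1 (676 against 167, 1.98), hesx1 (111 against 32.4, 1.63), six1a (101 against 34.4, 1.43), sox9b (1.08) and pax7a (216 against 102, 1.04). The lower ones were six6b (−1.42), sox3 (149 against 350, −1.21) and lhx4 (59.1 against 131, −1.08). prop1 (−0.51), pou1f1 (180 against 202, −0.16), pitx3 (−0.29), LHX3 (−0.36) and sox2 (−0.15) were among those that passed neither limit. These values pool progenitor-like and hormone-cell-like cells, whose shares differed between the libraries. Read within each class, chosen after seeing the data, six1a was called higher in neither. sox3 was called lower in hormone-cell-like cells alone, and there its log2 ratio was −0.30 without cluster 27.

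Signalling lists held few genes past the 2-fold rule. Notch genes (2 of 27 higher, 3 lower, median −0.34) included dll4 (1.63) and her15.1 (1.32) higher and notch1b (−1.28), dla (−1.17) and nrarpb (−1.16) lower. FGF genes (2 of 15 higher, 1 lower, median −0.37) included fgf8a (1.61) and fgf24 (1.1) higher and the target etv4 (−1.44) lower. Hedgehog genes had none past the limit of 8 (median −0.28), and these 3 medians and that of epithelial junction genes (2 of 18 lower, krt18a.1 and krt8, median −0.38) lay below the random range but turned positive within progenitor-like cells alone, while those of Notch (−0.68) and epithelial junction genes (−0.58) stayed negative within hormone-cell-like cells. BMP genes (id4 1.50 and bmp4 1.00 higher, id1 −1.05 lower, of 10, median −0.09), Wnt genes (apcdd1l 2.1 higher, of 6, median −0.06), p53 genes (bbc3 1.78 higher, tp53 −1.09 lower, of 9, median 0.52), oxidative phosphorylation (none of 26, median −0.04) and endoplasmic reticulum genes (ddit3 2.03 and atf4b 1.66 higher, of 27, median 0.24, negative with median-of-ratios scaling) lay within it. The dissociation stress list was higher in 10 of 29 and lower in 1, egr2a (median 0.46, percentile 99.99). Of its 7 heat shock members 5 were higher (median 4.45), with hsp70l at 2338 against 15.3 CPM (6.85), and of the other 22 genes 5 were higher (median 0.37). Of the receptors nr3c1 alone was measured (1.14, higher), and of the yolk list apoeb (−0.75), ctsla (−0.32) and h1m (1.50).

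**Figure D3:**
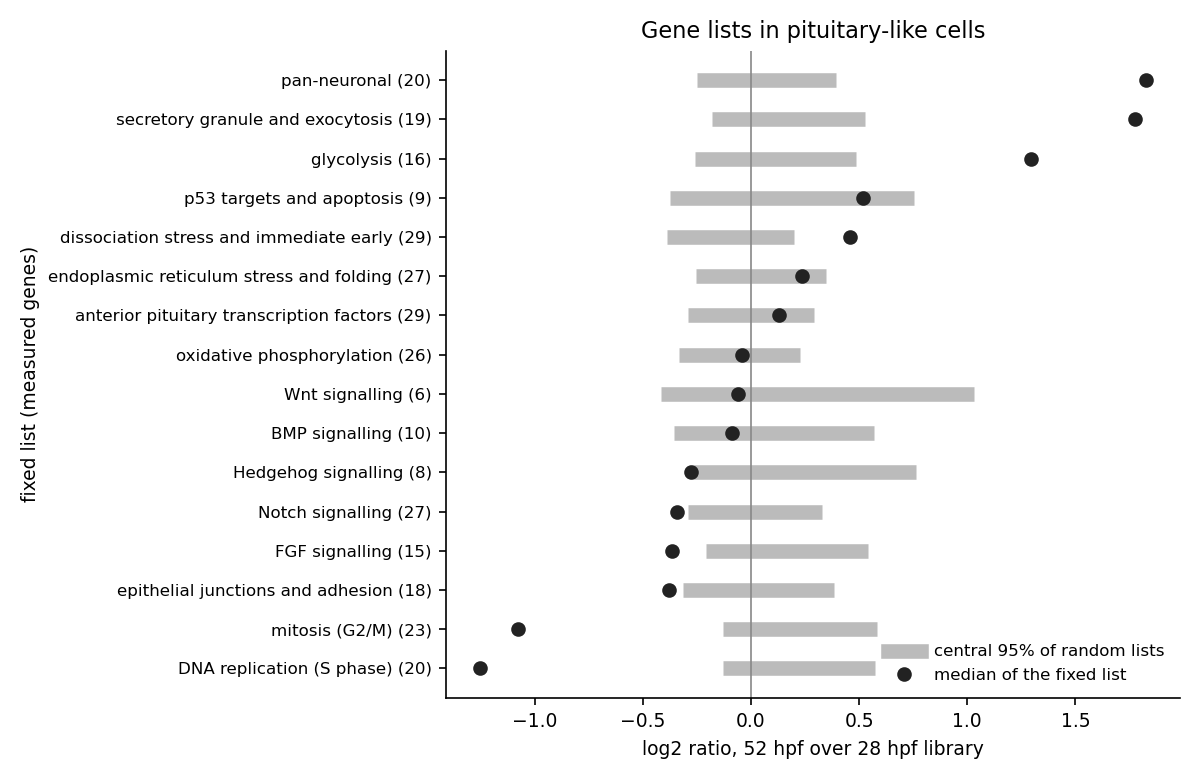
Median log2 ratio (52 over 28 hpf, x axis) of each fixed list in pituitary-like cells (y axis, measured genes in brackets) as a black point, with the central 95% of medians of 10000 expression-matched random lists as a grey bar. Pan-neuronal (1.83), secretory (1.77) and glycolysis genes (1.29) lay to the right of their bars, and mitosis (−1.08) and DNA replication genes (−1.25) to the left.

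By the naming rule, the 15 lowest genes in pituitary-like cells were cela1.6 (−4.57), smtla (−4.38), si:ch73-380l10.2, actc1c, the claudin cldn1 (−3.57), the keratin krt18a.1 (50.9 CPM at 52 hpf against 622, −3.49), lin28a (2.5 against 77.0, −3.45), the prostaglandin synthase gene ptgs2a (−3.19), cxcl12b (−2.92), fstl1a, tnnc1b, sost (−2.58), cldni (−2.53), agr2 and the growth factor midkine mdka (79.7 against 439, −2.39). The 15 highest were gh1, pvalb5 (6.96), hsp70l, oacyl (6.42), s100t (5.99), stmn4l (5.98), hsp70.1 (5.87), cga (5.40), hsp70.2 (5.32), gpm6aa (5.06), pomca (5.02), CR936442.1, BX511021.1, si:dkeyp-86h10.3 and gpm6ab (4.61).

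The genes that went with each hormone were found by comparing hormone-rich cells with progenitor-like cells rich in no hormone. Cells rich in 1 hormone alone numbered 120 for prl at 28 hpf, against 623 progenitor-like cells, and 45 for prl, 46 for tshba and 64 for pomca at 52 hpf, against 135. With 9 gh1-rich and 4 cga-rich cells those groups were too small. In all 4 comparisons secretory granule genes were higher, in 16 of 16 for prl at 28 hpf (median 4.22), 18 of 19 for prl at 52 hpf (2.57), 20 of 20 for tshba (2.85) and 22 of 22 for pomca (2.90). DNA replication genes were lower in 22 of 22 (−2.38), 10 of 20 (−1.01), 14 of 20 (−1.35) and 17 of 20 (−2.08), and Notch genes in 23 of 27, 17 of 26, 20 of 26 and 19 of 26. These medians lay beyond all 10000 random lists. Mitosis genes were lower in 24 of 24 for prl at 28 hpf (−3.38), 20 of 23 for tshba (−2.30) and 19 of 23 for pomca (−1.55), but in only 2 of 24 for prl at 52 hpf (−0.44). The 45 prl-rich cells at 52 hpf include 7 outside pituitary-like clusters, with a median doublet score of 0.208 against 0.0288 for the 38 inside. These list values were read with those 7 cells, so the mitosis value may carry RNA of other cells. More anterior pituitary transcription factors were lower than higher: 13 lower and 4 higher of 26 for prl at 28 hpf (median −0.99), 14 and 7 of 31 for prl at 52 hpf (−0.75), 16 and 7 of 29 for tshba (−1.27) and 11 and 8 of 29 for pomca (−0.16, within the random range). The list holds the progenitor markers by which progenitor-like clusters were named, so these counts and medians are partly set by the choice of those cells. prop1, one of those markers, was lower in each comparison, with log2 ratios of −2.26, −3.21, −4.48 and −4.51. At 28 hpf 20 of the 122 prl-rich cells lay in cluster 27, whose cells may be attached pairs and whose prop1 level was 270 CPM. In cluster 15, which held 100 of them, prop1 stood at 13.6 CPM, so the 28 hpf prl-rich values may carry RNA of progenitor-like cells.

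pomca-rich cells at 52 hpf had the T-box factor tbx19 (65.8 CPM against 0.618, 3.65), neurod1 (1608 against 156, 3.33) and pax7a (937 against 103, 3.12) higher, together with insm1a, insm1b, dlx3b, six1a and ascl1a. The prohormone convertase pcsk2 (126 against 0.618 CPM, 4.55), scg5 (843 against 25.4, 4.80) and the Notch ligand dll4 (206 against 5.57, 4.32) were higher too. Of 6 receptors measured, 5 were higher: the corticotropin-releasing hormone receptor crhr1 (60.7 against 4.33 CPM, 2.82), the dopamine receptors drd2b (45.5 CPM against 0 UMIs) and drd4a (2.17), the thyrotropin-releasing hormone receptor trhra (42.1 CPM against 0 UMIs) and the glucocorticoid receptor nr3c1 (1.56). The somatostatin receptor sstr5 was lower (−3.15). The 10 highest genes were the retinoic acid-binding gene crabp1a (6.28), oacyl (6.0), si:dkey-248g15.3, lin7a, anxa5a, si:ch211-207l14.1, scg5, BX005003.1, tmeff2a and AL590149.1. UMIs of these genes were found in 24 (si:ch211-207l14.1) to 62 (scg5) of the 64 cells, and of crabp1a in 28. The pooled levels therefore need not describe every pomca-rich cell.

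tshba-rich cells at 52 hpf had six1a (260 CPM against 15.5, 3.70), pou1f1 (477 against 38.3, 3.48), isl1 (479 against 45.8, 3.25) and gata2a (268 against 35.9, 2.74) higher, with insm1a, neurod4 and neurod1. Their 10 highest genes were the thyroid hormone deiodinase dio2 (7.40, UMIs in 46 of 46 cells), rgs16 (6.62), tbx3a (6.39), otpa (UMIs in 3 of 46 cells), neurog1 (5.87), zgc:56628, pdgfra (5.53), the galanin receptor galr1a, vsx1 (UMIs in 3 of 46 cells) and cga (3083 against 89.1 CPM, 5.04).

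prl-rich cells shared high neurod1 (788 CPM against 13.5 at 28 hpf, 859 against 156 at 52 hpf), pou1f1 (453 against 55.8, and 361 against 38.3), six1a and insm1a over progenitor-like cells at both ages, and at 52 hpf neurod4, gata3 and six6b were higher too, but on UMIs in 5, 2 and 7 of 45 cells, as was the retinal gene crx, chosen after its values were seen (85.4 against 1.86 CPM, UMIs in 3 cells). The natriuretic peptide-like gene nppal led at both ages, with log2 ratios of 7.25 at 28 hpf (UMIs in 47 of 120 cells) and 8.93 at 52 hpf (40 of 45), and tfcp2l1 was among the 10 highest at both (6.40 and 5.80). The other 8 at 28 hpf were si:ch73-380l10.2, ckbb, kctd12.1, si:ch211-153b23.5, si:ch211-251f6.6, nme2b.2, scg3 (5.68) and si:ch211-119o8.4. At 52 hpf they were BX322657.3, vsx1 (UMIs in 7 of 45 cells), cort (5.22), the membrane estrogen receptor gper1 (5.12), ptn, si:ch211-113g11.6, or137-3 (1 cell) and hepacam2. Of the 45 cells at 52 hpf, 7 lay outside pituitary-like clusters, with a median doublet score of 0.208 against 0.0288 for the 38 inside, and without them vsx1 and hepacam2 left the 10 highest.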

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

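All tests of explanations in this part were chosen after the results were seen.

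These results stood out because the same comparison pointed opposite ways in the libraries or cell classes compared; the differences were not tested, since each side is 1 library. Between prl-rich and progenitor-like cells, apoeb had log2 ratios of −2.90 at 28 hpf and 1.2 at 52 hpf, a difference of 4.11, with 85.3% of its UMIs in the 52 hpf prl-rich cells from 1 cell and −1.34 over rich cells inside pituitary-like clusters. cldni had −3.89 and 2.1 (difference 5.99), with 84.0% from 1 cell and −0.17 inside those clusters. krt18a.1 had −3.51 and 1.31 (difference 4.81) and 0.93 inside them. krt91 had −3.50 and 1.08 (difference 4.57) and 0.70 inside them. six6b had −3.37 and 2.95 (difference 6.31), with 56.9% from 1 cell and 1.86 inside them. smtlb had 5.59 and −2.86 (difference −8.44), and 105 of the 113 smtlb UMIs in 52 hpf progenitor-like cells came from 1 cell. That cell also stands behind the smtlb ratio of 52 over 28 hpf in progenitor-like cells, 3.56, against −2.35 in hormone-cell-like cells (difference −5.91). The growth cone gene gap43 was higher at 52 hpf in progenitor-like cells (141 against 56.2 CPM, 1.26) and lower in hormone-cell-like cells (282 against 769 CPM, −1.43), a difference of −2.69. No single cell carried its 52 hpf progenitor-like level, the highest holding 5.18% of those UMIs. The share of the highest cell was not computed for the other groups compared.

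The first pattern is a set of 28 hpf cells with both prl and progenitor genes, cluster 27 (54 cells, median 29589 UMIs and 5003 genes, doublet score 0.129), with 7979 CPM of prl, 270 CPM of prop1 and 20 prl-rich cells. The other pituitary-like clusters of that library had median doublet scores of 0.0150 to 0.0423. Droplets that caught 2 cells at random would have put about 18.7 prl-rich cells outside the pituitary-like clusters, where 0 were seen (upper limit 3.69). That count argues against them only if such pairs stayed among the kept cells and clustered outside, which is not known. Random pairs are therefore not excluded. Attached pairs of pituitary cells may explain the set: its UMIs were 1.95 times the highest median of the other hormone-cell-like clusters, and 0 of 2289 genes were 2-fold above all other pituitary clusters. Those clusters had 11 to 377 such genes, but each was compared with the rest without cluster 27. Their counts were thus read against fewer clusters and are not a like comparison. Its depth stood out less from progenitor-like cluster 10, which had a median of 21393 UMIs. Single cells between the progenitor and the hormone-cell state cannot be told apart from such pairs, since 99.8% of genes lay within 2-fold of a mixture of the other clusters (47.1% cluster 0, 26.4% cluster 7, 25.5% cluster 15), which a transition could also give. The biological reading is therefore open and this set is no evidence of a transition.

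The second pattern is the level of the hsp70 genes, 6650 CPM at 52 hpf against 320 CPM at 28 hpf (20.8-fold, 20.3–21.2). A different mix of cell types is argued against, because in each of the 5 groups of cells present in both libraries the genes were higher at 52 hpf, the lowest log2 ratio being 3.93 in cluster 3. A few damaged cells are argued against too, because the median 52 hpf cell held 5648 CPM. Handling or dissociation that differed between the libraries, with a fold of at least 15.4 in every one of those groups, cannot be told apart from the age of the embryos, since each age is 1 library. Age itself stays open and untested.

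The third pattern is smtla, 96.6-fold higher in the 28 hpf library. Fewer prl cells at 52 hpf are argued against as the whole cause, because within prl-rich cells smtla stood at 768 CPM at 28 hpf and 35.6 CPM at 52 hpf (1571 and 20 UMIs), 21.6-fold (13.9–35.4), while prl was 33147 and 40166 CPM. Reads assigned to the paralog smtlb instead are argued against, because smtlb was lower in the same 52 hpf cells as well, 5.34 against 275 CPM, 51.6-fold (17.6–251). Both tests cover prl-rich cells alone, which held 1571 of the 4348 smtla UMIs at 28 hpf. Cluster 7, with 2 prl-rich cells among 170, held 1890, and whether such cells were fewer at 52 hpf was not tested. A difference of age is a further hypothesis, untested with 1 library per age, and a difference of the batch of embryos cannot be separated from it.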

How the results depend on the processing

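Alternatives named here as added were chosen after seeing the data, and the others before the data were examined. No paired analysis was possible because each group holds 1 library and no result comes from a test, and leaving out a library was not possible for the same reason. Among results that answer a comparison, 141 alternative values stayed within the counting interval of the main value, 73 moved beyond it and 1 turned its direction. Among the other results the numbers were 624, 256 and 6. For list medians a turn was counted only where the main median lay outside the central 95% of random lists, so medians within that range that changed sign are counted by size alone. The 52 hpf library holds 9 gh1-rich and 11 cga-rich cells, and the limits of 3 counts are 0.105 CPM at 28 hpf and 0.0742 CPM at 52 hpf. With a hormone threshold of 0.5% the hormone list in tshba-rich cells had too few measured genes to give a value. Pituitary-like shares ranged from 61.4% to 62.4% at 28 hpf and from 16.1% to 16.7% at 52 hpf over all alternatives.

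Hormone log2 ratios, 52 over 28 hpf, depended on which cells were the denominator and, for genes with few UMIs, on the pseudocount. Over UMIs of pituitary-like cells alone (added) prl turned from −1.91 to 0.14, because that denominator leaves out the other cells, and tshba was 4.06, pomca 5.02, cga 5.40, smtla −4.38 and smtlb −1.12. With median-of-ratios scaling prl was −2.0, tshba 1.84, pomca 2.75 and cga 3.07. With totals that leave out hormone, globin and ribosomal protein genes they were −2.03, 1.81, 2.73 and 3.05. With a pseudocount of 20 CPM (added for these ratios) prl was −1.89, tshba 1.84, pomca 2.59, cga 2.45, smtla −3.00 and smtlb −2.15, and with 1 CPM (added for these ratios) smtla was −5.90. Filters moved them in the last digits: pomca was 2.84 and cga 3.15 with no filter on cells, smtla −4.58 and smtlb −2.88 with doublets kept, and smtlb −2.89 with the strict filter.

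The share of thinned cells with a prop1 UMI was 22.2% at 28 hpf and 3.26% at 52 hpf at 3000 UMIs, since fewer UMIs per cell are read. With a hormone threshold of 2%, prl-rich cells at 28 hpf were 6.40%, tshba-rich 0.129% and pomca-rich 0%, and at 52 hpf pomca-rich cells were 1.72% and cga-rich 0.0336%. At 0.5%, pomca-rich cells were 0.453% at 28 hpf and cga-rich cells 1.65% at 52 hpf. As shares of pituitary-like cells (added), prl-rich cells were 12.7% at 28 hpf and 8.47% at 52 hpf, and at 52 hpf tshba-rich cells were 11.5%, pomca-rich 13.3%, cga-rich 2.22% and gh1-rich 1.61%.

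In pituitary-like cells the secretory median (1.77) was 1.51 and the DNA replication median (−1.25) −1.53 with median-of-ratios scaling. They were 1.63 and −1.41 without hormone, globin and ribosomal protein genes, 1.92 and −1.34 with a pseudocount of 1 CPM, and 1.33 and −0.99 with 20 CPM. The secretory median was 1.65 with no gene filter and 1.90 without cluster 27 (added), and the DNA replication median −1.39 in thinned cells. In progenitor-like clusters alone (added) they were 2.37 and −0.63, without hormone-rich cells (added) 2.15 and −0.61, and in hormone-cell-like clusters alone (added) 1.29 and −0.95. There the medians of smaller size turned, whether or not the tally counts them: in progenitor-like clusters Notch was 0.13, Hedgehog 0.38, FGF 0.16, BMP 0.20, Wnt 0.39 and epithelial junctions 0.26, and in hormone-cell-like clusters FGF was 0.035, BMP 0.52 and the endoplasmic reticulum list −0.16. Notch (−0.68) and epithelial junctions (−0.58) stayed negative in hormone-cell-like clusters. The cause was not tested. Over the whole library the DNA replication median (−0.35) was −0.43 with median-of-ratios scaling, −0.46 without hormone, globin and ribosomal protein genes, −0.38 and −0.24 with pseudocounts of 1 and 20 CPM, and −0.43 in thinned cells.

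The secretory median of hormone-rich over progenitor-like cells stayed positive throughout. With median-of-ratios scaling it was 2.63 for tshba, 2.67 for pomca and 3.98 for prl at 28 hpf. With a pseudocount of 1 CPM it was 2.90 for prl at 52 hpf, 3.16 for tshba, 3.28 for pomca and 5.46 for prl at 28 hpf, and with 20 CPM 2.0, 2.31, 2.37 and 2.80. At a threshold of 2% it was 2.04 for prl at 52 hpf, 3.04 for tshba and 4.44 for prl at 28 hpf. The median of the hormone list in pomca-rich cells turned from −1.66 to 1.05 at a threshold of 0.5%, and the cause was not tested.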

Other observations

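No explanation is tested in this part, and its comparisons within 1 pituitary class or between clusters were chosen after the data were seen.

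Progenitor-like cells were read on their own (623 cells mostly in clusters 0 and 10 at 28 hpf, 144 cells mostly in cluster 9 at 52 hpf). Of 27 pituitary transcription factors measured there, 5 were higher at 52 hpf: neurod1 (3.31 on the log2 scale), hesx1 (262 against 41.2 CPM, 2.53), sox9b (1.67), otx2b (1.32) and isl1 (1.27). six6b (−2.00) and lhx4 (−1.07) were lower, and prop1, a marker by which the clusters were named, passed neither limit (0.48). Of 26 Notch genes, 4 were higher, her15.1 (1.76), her6 (1.50, 4453 against 1571 CPM), her4.3 (1.27) and her4.2 (1.17), and notch1b was lower (−1.26), with a list median of 0.13 that lay within the random range. Among signalling genes, apcdd1l (3.27), the ligand fgf8a (271 against 51.1 CPM, 2.3), hhip (1.81) and cdon (1.48) were higher and wnt11 (−2.48) was lower, and the somatostatin receptor sstr5 was higher (51.8 against 1.57 CPM, 3.11). DNA replication genes were lower in 6 of 22 (median −0.63) and mitosis genes in 3 of 25 (median −0.60). The genes lowest at 52 hpf included cela1.6 (−4.81), the collagens col14a1a (−4.59) and col1a1a (−2.76), the claudins cldn1 (−4.25) and cldni (−3.22) and the keratins krt18a.1 (−3.45), krt92 and cyt1l. The epithelial junction list as a whole was not lower, with 1 of 20 lower, 1 higher and a median of 0.26. Hormone transcripts were also higher in the progenitor-like cells at 52 hpf, prl at 959 against 22.6 CPM and pomca at 695 against 8.22 CPM. Without the hormone-rich cells in those clusters the 52 hpf levels were 170 CPM for prl and 191 CPM for pomca. Over all cells outside pituitary-like clusters of the same library they were 85.4 and 28.1 CPM. That prl level includes 7 prl-rich cells, so it is not a like background for the 170 CPM. The 45 cells rich in prl alone held 22583 prl UMIs and the 38 of them inside pituitary-like clusters 20091, beside 3009 prl UMIs outside in all.

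Hormone-cell-like cells (339 at 28 hpf, 352 at 52 hpf) had isl1 (1.80), pax7a (1.66), gata2a (1.63) and neurod1 (1.1) higher at 52 hpf and prop1 (−2.50) and sox3 (−1.32) lower, of 27 transcription factors measured. Without cluster 27, which held 469 of the 538 prop1 UMIs at 28 hpf, isl1 (1.62), pax7a (1.78) and gata2a (1.50) were still higher, but neurod1 (0.89), prop1 (−0.41) and sox3 (−0.30) passed neither limit. Secretory granule genes were higher in 12 of 21 and lower in none (median 1.29), with chga at 421 against 42.0 CPM. Notch genes went both ways, 3 of 21 higher, her15.1 among them (1.98), and 6 lower, her12 (−1.88) and hes6 (−1.45) among them, with a list median of −0.68 below all 10000 random lists. The epithelial junction median was −0.58 (percentile 0.01). The translocon genes ssr3 (−1.05) and sec61b (−1.0) were lower, ddit3 (1.74) and atf4b (1.66) higher.

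Of 6798 cga UMIs at 52 hpf, 3013 lay in cluster 24 and 2540 in cluster 25, named here after their values were seen. Of the 316 cells with a cga UMI those clusters held 66 and 58. In cluster 25 (63 cells) cga (3673 CPM) stood beside tshba (27865 CPM), pou1f1 (447 CPM) and dio2 (883 CPM). In cluster 24 (66 cells) a cga UMI was found in 66 of 66 cells (5188 CPM), while tshba stood at 907 CPM with 49.7% of its UMIs from 1 cell, pou1f1 at 17.2 CPM and dio2 at 10.3 CPM. isl1 was at 1014 CPM in cluster 24 and 503 CPM in cluster 25, gata2a at 827 and 252 CPM, chga at 990 and 375 CPM, the calcium-binding gene scgn at 839 and 370 CPM, tbx20 at 520 and 111 CPM, and the opioid precursor penkb at 346 and 28.9 CPM. Neither cluster held a UMI of lhb or of nr5a1b, the gene of a gonadotroph transcription factor. The clusters were drawn partly by these genes, so the values describe the clusters and test nothing. The cells rich in smtlb at 52 hpf were 3, with 249 smtlb, 3 smtla and 43 prl UMIs between them.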
